A study of Homo sapiens with 4 samples.

How the data were processed

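Total RNA of KYSE410 cells, a line from a human esophageal squamous cell carcinoma, was measured on 4 Affymetrix 3' expression arrays. Biotin-labelled cRNA was made from 200 ng of total RNA, per the labels' protocols. The samples were grouped by their titles (untreated or treated), and their treatment labels name the drug: 2 untreated and 2 treated with YM155, at 20 nM for 6 h. The treatment protocol in the labels names another drug, cisplatin at 10 mM for 12 h, and the design text names both drugs. The treatment labels, source names and series title, which name YM155, are followed here. The titles of the YM155 arrays also hold the codes B1 and B2, which the labels do not explain and which were not used. The labels name no culture, day or array batch, so a p-value here measures the spread between these arrays, which may be technical.

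The authors deposited 1 intensity per probe set and array, made with robust multi-array averaging (RMA) per the submitters' processing notes. The RMA version and its settings are not given in the sources used here. RMA usually gives log2 values, but the deposited intensity values ran from 2.42 to 15214 and were on a linear scale, so log2 was taken before any test. RMA has already set the arrays to a common distribution: the array medians lay between 16.0 and 16.3. A shift shared by all genes is therefore not measured, and each difference is relative to the other genes on the array. Scanner files and detection calls were not used here. The number of arrays limits the precision: with 2 per group, each gene's own spread rests on 2 residual degrees of freedom.

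The table held 54675 probe sets, of which 62 were control probe sets and were left out. Gene names came from the platform annotation: 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none. Of the probe sets with 1 symbol, 41037 matched a RefSeq gene by gene ID, and no symbol needed an update. Probe sets with several symbols named no gene. Probe sets whose mean log2 value over the 4 arrays lay below the 40th percentile were left out, which kept 32768. Each gene was represented by its probe set of highest mean, which gave 14043 genes. No coordinates are given, because the sources used here name no genome build for the probe sets.

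YM155 was compared with untreated using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over 14043 genes and a threshold of 0.05. The prior contributed 2.69 degrees of freedom. Log2 differences are YM155 minus untreated, with their standard error (SE) from limma. Gene lists fixed before the data were examined, 21 in number, were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists. They were tested again with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move one way on balance. Within each list, the limma p-values were also adjusted over the list alone. Nothing was adjusted across the 21 lists for these calls of single members, so their error rate over all lists is not controlled. A list of genes linked to YM155 and lists of fibroblast, leukocyte, endothelial and glandular epithelium markers were described without a test.

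The genes named were set by a rule written before the data were examined. It took BIRC5, and the 12 genes with the largest positive and the 12 with the largest negative differences among those past the threshold whose arrays did not overlap. Uncharacterised loci were passed over. Where too few passed, the next by size with an unadjusted p under 0.05 were taken and are said not to have passed. The rule also took up to 4 members of each tested list by absolute difference, all members of the list linked to YM155, and the 2 brightest markers of each other cell type. Genes named outside this rule are members adjusted over their list alone, or are said to have been chosen after their values were seen.

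The gene test was checked on simulated data: for YM155 against untreated, values of 14043 genes were drawn with variances from the fitted prior. It recovered 5 of 100 genes changed by 1 log2 and 83 of 100 changed by 2 log2, with 4 false calls. The simulated genes were independent and had the same variance in both groups. In the real data the variance of the log2 difference was 0.239 between the untreated arrays and 0.054 between the YM155 arrays. The simulated recovery and false calls therefore need not hold for the real data. Alternatives fixed beforehand were no filter or a filter at the 60th percentile, the mean of a gene's probe sets, only probe sets without the _x_at or _s_at suffix, a second quantile normalization, centring on the median, eBayes with trend and robust (for lists, camera with a trend in variance), the replicate number as a block, each array left out in turn, and all probe sets tested one by one. Array weights and the ACTB 3' to 5' signal ratio as a covariate were added after the data were seen. For a list, direction across alternatives was read from the sign of its mean difference, a definition set after the data were seen. Medians of gene groups were placed among those of 10000 random lists of equal size, matched on mean signal in 20 bins, with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.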

Results

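Gene expression was profiled in KYSE410 cells, an established human esophageal squamous cell carcinoma line, left untreated or treated with 20 nM YM155 for 6 h. YM155 is a small molecule first described as a suppressor of the expression of survivin, the apoptosis inhibitor encoded by BIRC5. The series held 2 untreated and 2 YM155 arrays, and the comparison asked which transcripts differed between the groups. The 2 YM155 arrays were at least 2-fold apart at 56 of 32768 probe sets, and the 2 untreated arrays at 1690. Untreated replicate 1 was nearer to the YM155 arrays (739 and 850 probe sets) than to untreated replicate 2. The treatment protocol in the labels names cisplatin, whereas the treatment labels, source names and series title name YM155, which is followed here.

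BIRC5 was not detectably different between the groups: its mean log2 value was 9.53 ± 0.28 (SD, n = 2) in untreated and 9.27 ± 0.04 (SD, n = 2) in YM155 arrays, a difference of −0.26 ± 0.18 (SE; limma adjusted p = 0.615). Its 4 probe sets had differences between −0.54 and −0.10. Among annotated genes with an unadjusted p under 0.05 and arrays that did not overlap, the largest positive differences belonged to HMOX1, the heme-degrading enzyme heme oxygenase 1, at 2.49 ± 0.39 log2 (SE), GRHL3, a transcription factor of epidermal differentiation, at 3.26 and 3.40 log2 in untreated and 5.82 and 5.62 in YM155 arrays, SLC30A1, a zinc exporter, at 2.32 ± 0.33, and CITED2, a transcriptional coregulator, at 2.30 ± 0.21. The largest negative ones belonged to ID1, an inhibitor of basic helix-loop-helix factors, at −2.81 ± 0.23, DDIT4, a stress-induced inhibitor of mTORC1, at −2.52 ± 0.23, MIR205HG, a microRNA host transcript, at −2.41 ± 0.61, and DBP, a clock-controlled transcription factor, at −2.36 ± 0.40. None of these genes passed the adjusted threshold.

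Further positive differences without overlap of the arrays were found for INSIG1, which restrains sterol synthesis (2.21 ± 0.68), PLAUR, the urokinase receptor (2.01 ± 0.60), the RNA helicase gene DDX5 (1.96 ± 0.27), the interleukin-6 receptor gene IL6R (1.94 ± 0.30) and DUSP1, a MAP kinase phosphatase (1.85 ± 0.32). EFNB2, an ephrin ligand, stood 1.81 ± 0.14 higher, NR4A3, an orphan nuclear receptor, 1.76 ± 0.40, and the secreted protease gene ADAMTS1 1.72 ± 0.58. On the other side stood PAQR8, a membrane progesterone receptor (−2.25 ± 0.21), EHF, an epithelial ETS factor (−2.04 ± 0.20), YPEL2 (4.34 and 5.90 log2 in untreated, 3.33 and 3.22 in YM155 arrays), VAV3 (−1.83 ± 0.31), TNFAIP8L1 (−1.82 ± 0.41), PLLP (−1.72 ± 0.14), the lipoprotein receptor gene VLDLR (−1.71 ± 0.23) and KBTBD3 (−1.65 ± 0.47). Some of these values depended on which untreated array was the reference. INSIG1 was at 6.77 and 8.80 log2 in untreated replicates 1 and 2, and at 9.89 and 10.1 in the YM155 arrays. Over the arrays left out, the differences ran from 1.19 to 3.22 for INSIG1, 0.87 to 2.57 for ADAMTS1, 1.18 to 2.83 for PLAUR, −2.63 to −1.06 for YPEL2, −2.34 to −0.97 for KBTBD3 and −3.30 to −1.52 for MIR205HG. ID1 was at 8.37 and 8.38 in the untreated arrays and at 5.85 and 5.27 in the YM155 arrays. GRHL3 in untreated and YPEL2 in YM155 arrays lay at the filter's limit of 3.32 log2, a signal not shown to exceed background, so the sizes of their differences are not exact. Other probe sets did not always agree: they gave −0.16 for CITED2, −0.048 and 0.20 for DUSP1 and 0.13 for ADAMTS1, and smaller differences for PLAUR (0.61), INSIG1 (0.97), PAQR8 (−0.87) and EHF (−0.75). Those of CITED2 (5.2 to 5.4 log2) and DUSP1 (4.1 to 5.0 log2) were dimmer than the ones used. Further probe sets lay nearer to the values above, at 1.46 for CITED2, 1.87 for PLAUR, 1.82 for INSIG1 and −1.67 for EHF. DBP gave 0.022 when only probe sets without the _s_at or _x_at suffix were used, from a dim probe set at 4.0 to 4.1 log2. For DDX5, a brighter probe set annotated with several genes named no gene here, and it gave 1.32.

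**Figure D1:**
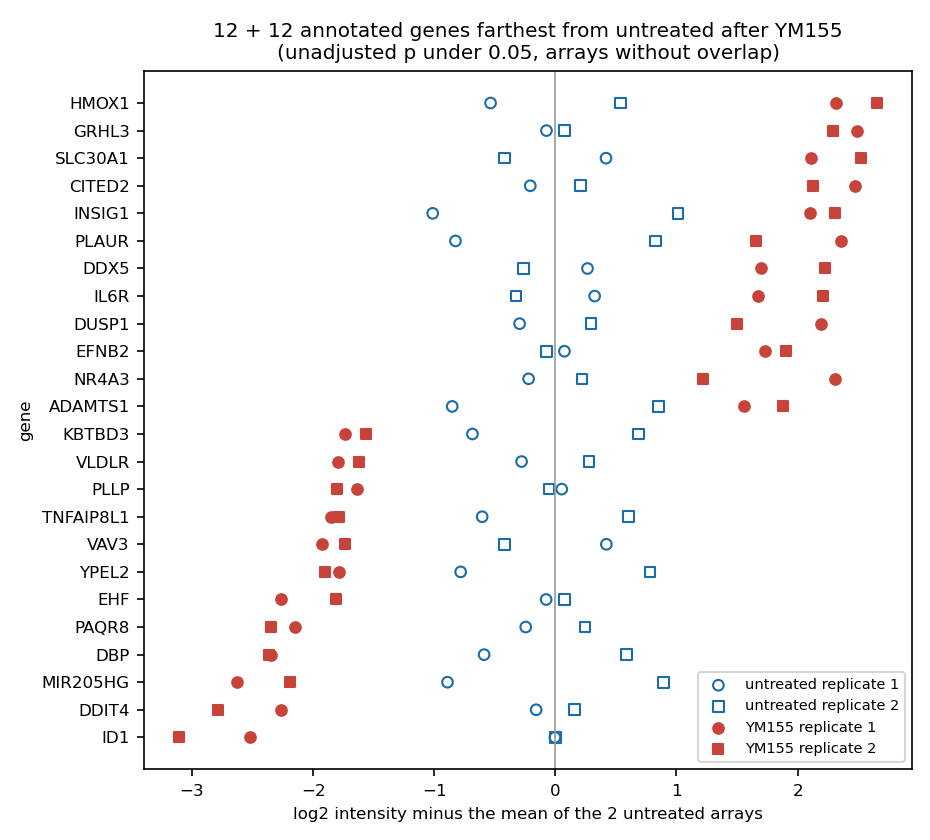
Each gene's log2 intensity on the 4 arrays minus the mean of its 2 untreated arrays (horizontal axis), for the 12 annotated genes farthest above and the 12 farthest below untreated among those with an unadjusted p under 0.05 and no overlap; open symbols are untreated and filled symbols YM155 arrays, circles replicate 1 and squares replicate 2. The filled symbols lie on 1 side of the open ones for each gene, and the open symbols are far apart for INSIG1 (6.77 and 8.80 log2) and together for ID1 (8.37 and 8.38 log2).

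By limma, 0 of 14043 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.163. At an unadjusted p under 0.05 there were 1785 genes, 734 higher and 1051 lower, where 702 would be expected by chance. Of these, 115 were at least 2-fold higher and 130 at least 2-fold lower. The YM155 arrays both lay above both untreated arrays for 2712 genes and below them for 3597, together 44.9% of genes, where chance gives 33.3%. The 24 genes named above for their size had adjusted p between 0.163 and 0.347. Without untreated replicate 1, limma called 604 genes higher and 521 lower, among them ID1, DDIT4, GRHL3 and HMOX1, whereas leaving out any other single array gave 0 in both directions. In that fit, a lone untreated array is assumed to vary like the YM155 arrays.

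Most mitotic genes had lower values after YM155, and most ribosome assembly and squamous differentiation genes higher ones. Of 56 genes of the G2 and M phases, 52 had negative differences, with a mean of −0.46 log2. Camera called this list lower (adjusted p = 1.66e-09), but not with its correlation estimated (adjusted p = 0.706 with an estimated correlation). Its largest differences were those of PSRC1 (−1.36 ± 0.32 SE), HJURP (−1.17 ± 0.52), NDC80 of the kinetochore (−1.12 ± 0.14) and the mitotic phosphatase gene CDC25C (−1.05 ± 0.22). Of 25 ribosome biogenesis genes, 23 had positive differences, with a mean of 0.38 (camera adjusted p = 9.47e-07, adjusted p = 0.706 with an estimated correlation). They were led by NIP7 (1.04 ± 0.23), RRS1 (0.73 ± 0.28), POLR1A, the largest subunit of RNA polymerase I (0.73 ± 0.44), and BYSL (0.69 ± 0.13). Of 20 squamous differentiation genes, 17 had positive differences, with a mean of 0.45 (camera adjusted p = 2.45e-05, adjusted p = 0.706 with an estimated correlation). The squamous list's estimated correlation was 0.0070, below the preset 0.01. Its call therefore ended for want of degrees of freedom (2), not through correlated genes. For G2 and M phase and ribosome biogenesis genes the estimated correlation was 0.50 and 0.51. In the squamous list the cornified envelope genes SPRR3 (1.30 ± 0.36) and SPRR1B (1.20 ± 0.42), EMP1 (0.89 ± 0.29) and the keratin gene KRT16 (0.76 ± 0.15) stood highest. The SPRR3 probe set was dim in untreated arrays (3.89 and 4.63 log2), and its other probe set gave 0.20.

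No member passed over all genes, in these lists or in any of the 21 tested. Adjusted over the list alone, which leaves out that 21 lists were tested, CKAP2L and NDC80 fell in the G2 and M phase list, and 0 members changed in the other 2. The untreated arrays differed in these lists too: untreated replicate 2 differed from replicate 1 by 0.49 log2 in median for G2 and M phase genes, −0.37 for ribosome biogenesis genes and −0.19 for squamous genes. The median difference of the YM155 mean from untreated replicates 1 and 2 was −0.22 and −0.68 for G2 and M phase genes, 0.23 and 0.57 for ribosome biogenesis genes, and 0.20 and 0.50 for squamous genes. The sizes of some leading members depended on the untreated array: over the arrays left out, POLR1A ran from 0.084 to 1.38, RRS1 from 0.35 to 1.12, HJURP from −1.94 to −0.40, PSRC1 from −1.82 to −0.90, SPRR1B from 0.67 to 1.72 and EMP1 from 0.51 to 1.26.

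S phase genes had no common direction. Their mean was 0.0064 and their median −0.030 over 41 genes, and camera's adjusted p was 0.929. CCNE2, a cyclin of the G1/S transition, stood 1.42 ± 0.23 (SE) higher and BRIP1 0.66 ± 0.33 higher, while E2F8 stood at −0.50 ± 0.13 and PRIM1 at −0.45 ± 0.32. Histone genes had a mean of −0.25 with 21 of 29 negative (adjusted p = 0.0739), with H2BC21 at −1.62 ± 0.67 and H2AC8 at −1.16 ± 0.74. H4C8 went the other way (0.61 ± 0.14), without overlap of its arrays. Its probe set was dim (3.92 and 4.14 log2 in untreated arrays), and its other probe set gave 0.16. The histone list held 76 genes, most of which were not tested. The differences of H2BC21 and H2AC8 came mainly from untreated replicate 2, since over the arrays left out H2BC21 ran from −2.64 to −0.61 and H2AC8 from −2.27 to −0.051. PRIM1 ran from −0.88 to −0.026 and BRIP1 from 0.19 to 1.14. Genes of cytosolic ribosomal proteins (mean −0.013 over 54 genes, adjusted p = 0.929) and of oxidative phosphorylation (mean −0.052 over 72 genes, adjusted p = 0.331) stayed near 0. Most had small negative differences, 39 of 54 and 54 of 72. In these 2 lists the largest single differences were those of RPL39L (0.28 ± 0.42) and ATP5MF (0.50 ± 0.20), both from dim probe sets; ATP5MF ran from 0.27 to 0.73 over the arrays left out. The 326 zinc finger genes tested had a mean of −0.00076 and a median of 0.0060, with 168 positive (camera's direction up, adjusted p = 0.683), and ZNF451, ZNF565, ZNF365 and ZNF442 stood between 1.01 and 1.43 higher. For ZNF451 that value came from the brightest mean signal, and its next brightest probe set gave −0.73.

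Genes of protein folding had mostly positive differences, as had 14 of 21 NRF2 targets of the oxidative stress response, and several targets of the integrated stress response negative ones. The NRF2 list had a mean of 0.32 (camera adjusted p = 0.0181, adjusted p = 0.706 with an estimated correlation), but a median of only 0.13, which was 0.16 from untreated replicate 1 and 0.0063 from untreated replicate 2. In it, HMOX1, the glutathione synthesis gene GCLC (1.05 ± 0.12 SE) and SRXN1 (0.86 ± 0.14) rose when adjusted over the list alone. In the unfolded protein and heat shock list, 20 of 25 genes were positive, with a mean of 0.22 (camera adjusted p = 0.0032, adjusted p = 0.706 with an estimated correlation). The estimated correlation of this list was 0.0095, which like that of the squamous list lay below the preset 0.01. DNAJB9 (0.80 ± 0.15), DNAJA1 (0.79 ± 0.32), CRELD2 (0.67 ± 0.15) and DNAJB1 (0.62 ± 0.36) stood highest, and 0 members changed over the list alone. Among 27 integrated stress response genes, 14 had positive and 13 negative differences. DDIT4, VLDLR, CHAC1 (−1.60 ± 0.25), SESN2 (−1.18 ± 0.18) and DDIT3 (−0.82 ± 0.14), the gene of the stress factor CHOP, fell when adjusted over the list alone. Cholesterol synthesis genes had a mean of 0.26 over 18 genes, with HMGCS1 at 0.78 ± 0.30 and IDI1 at 0.69 ± 0.15 after INSIG1.

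Without untreated replicate 1 the calls of the NRF2 list and of the unfolded protein and heat shock list ended, at adjusted p of 0.431 and 0.243. DNAJB1 ran from 0.10 to 1.14, DNAJA1 from 0.34 to 1.24 and HMGCS1 from 0.37 to 1.19 over the arrays left out. The NRF2 call also ended without YM155 replicate 1 (adjusted p = 0.138). The integrated stress response list was not called (adjusted p = 0.331), except without untreated replicate 2, and its mean of −0.28 and median of 0.027 differed in sign. Its median lay at −0.39 from untreated replicate 1 and at 0.47 from untreated replicate 2, and the untreated arrays themselves differed by −0.99 in median (replicate 2 minus 1). Hypoxia and glycolysis genes were not called either (mean −0.22 over 28 genes, adjusted p = 0.331). ENO2 (−1.25 ± 0.64), BNIP3 (−0.97 ± 0.70) and ANKRD37 (−0.88 ± 1.02) stood low and the glycolytic regulator PFKFB3 (0.88 ± 0.14) high. ENO2 ran from −2.21 to −0.29 over the arrays left out, while BNIP3 (−2.02 to 0.090) and ANKRD37 (−2.43 to 0.66), whose arrays overlapped, changed sign. The list's median was 0.078 from untreated replicate 1 and −0.37 from untreated replicate 2. The cholesterol list had an adjusted p of 0.0509, and for LSS (0.51 ± 0.43) the probe sets went both ways.

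Differences of pro-apoptotic and anti-apoptotic genes were below 1 log2 in size in each gene's brightest probe set. Of 23 pro-apoptotic genes, 18 had negative differences, with a mean of −0.20 (camera adjusted p = 0.0373, adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, the death receptor gene FAS (−0.76 ± 0.14 SE) and the mitochondrial protease gene HTRA2 (−0.72 ± 0.13) fell and the TRAIL receptor gene TNFRSF10A (0.60 ± 0.12) rose, while HRK stood at −0.68 ± 0.19. The 14 anti-apoptotic genes had a mean of 0.11, with 7 positive and 7 negative, and FAIM at 0.85 ± 0.29, BAG1 at 0.39 ± 0.15 and BAG3 at 0.31 ± 0.23. Other probe sets of BAG1 gave 0.29 and 1.06. MCL1, an anti-apoptotic BCL2 relative, stood at 0.48 ± 0.31 in its brightest probe set, and all its probe sets were positive. One at 1.70 read 8.21 and 8.25 log2 in untreated and 9.81 and 10.0 in YM155 arrays. Another, at 1.49, read 5.22 and 5.28 in untreated and 6.68 and 6.80 in YM155 arrays. Targets of p53 went both ways: adjusted over the list alone, the exonuclease gene AEN (0.93 ± 0.12), the cell cycle inhibitor gene CDKN1A (0.91), TIGAR (1.05 ± 0.19) and EDA2R (0.69) rose, and SESN2 and FAS fell. GDF15, also in that list, stood at −1.31 ± 0.39. With each array left out in turn, the brightest probe set of MCL1 ran from 0.036 to 0.92, BAG3 from 0.026 to 0.60, FAIM from 0.49 to 1.22 and GDF15 from −1.76 to −0.86.

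Camera's call of the pro-apoptotic list as lower also ended without either untreated array (adjusted p = 0.119 and 0.133) or without YM155 replicate 2 (adjusted p = 0.111). The anti-apoptotic list (adjusted p = 0.37), the p53 list (mean 0.017 over 26 genes, adjusted p = 0.858) and the DNA damage response and repair list (mean −0.085 over 33 genes, adjusted p = 0.614) were not called. In the last, PARP2 (−0.79 ± 0.17), XRCC4 (−0.68 ± 0.37), CHEK2 (−0.56 ± 0.19) and TP53BP1 (−0.44 ± 0.22) had the largest differences, and over the arrays left out XRCC4 ran from −1.14 to −0.21, CHEK2 from −0.79 to −0.33 and TP53BP1 from −0.70 to −0.18. Of the genes that earlier work linked to YM155, the transcription factor gene SP1 stood lowest (−0.81 ± 0.26, adjusted p = 0.335). SLC35F2, the transporter that takes up YM155, was at 9.44 log2 in untreated and 9.52 in YM155 arrays. NONO (−0.020), ILF2 (−0.11), STAT3 (−0.12), AIFM1 (−0.13), PARP1 (−0.15), TOP2A (−0.31) and EGFR (0.21) lay between −0.31 and 0.21, and EGFR's probe sets had both signs. Leaving out each array gave −1.12 to −0.51 for SP1, −0.56 to −0.068 for TOP2A, −0.24 to −0.071 for PARP1, −0.24 to −0.011 for STAT3 and −0.46 to −0.061 for BIRC5.

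Immediate early genes stood higher, but in median by 1.10 log2 against untreated replicate 1 and by 0.093 against untreated replicate 2. Of 26, 19 had positive differences, with a mean of 0.60 (camera adjusted p = 0.000158, adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone, DUSP1, NR4A3, MYC (1.38 ± 0.34 SE), RHOB (1.20), JUN (1.10), KLF4 (0.82) and EGR3 (0.73) rose and IER3 (−0.87) fell. CCN2 stood at 1.70 ± 1.14. The MAP kinase feedback and growth factor list had a mean of 0.19 over 21 genes, with DUSP5 at 1.49 ± 0.76, FOSL1 at 1.09 ± 0.70 and ETV5 at −1.28 ± 0.31, and the receptor gene ERBB3 (−0.97) fell over the list alone. Targets of NF-kappaB were split: PTGS2, the inducible cyclooxygenase gene (1.15 ± 0.17), TNFAIP3, a feedback inhibitor (0.96 ± 0.12), and LIF (0.70) rose and IER3 fell over the list alone, while IL1A stood at −1.49 ± 0.40 and CCL20 at −1.0 ± 0.55. Of the interferon-stimulated genes, the interferon signalling factors IRF9 (−1.11 ± 0.12) and IRF1 (−0.90 ± 0.14) fell and OASL (0.97 ± 0.14) rose over the list alone, and IFIT3 stood at 0.82 ± 0.40.

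The 26 immediate early genes were all higher in untreated replicate 2 than in replicate 1 (median 0.79 log2), and without untreated replicate 1 the list's mean was 0.057 (adjusted p = 0.872). The differences of FOSL1 and DUSP5 came mainly from untreated replicate 1: over the arrays left out, FOSL1 ran from 0.027 to 2.15 and DUSP5 from 0.45 to 2.54, while ETV5 ran from −1.71 to −0.85, CCL20 from −1.81 to −0.20 and IFIT3 from 0.25 to 1.39. The MAP kinase list (adjusted p = 0.229), the NF-kappaB list (adjusted p = 0.94) and the interferon list (mean 0.073 over 22 genes, adjusted p = 0.37) were not called. For NF-kappaB targets the mean (−0.079) and median (−0.16) were negative while camera's direction was up. Markers of other cell types were dim in both groups, with median log2 levels between 4.01 and 4.71, and their median differences were −0.048 for fibroblast, 0.061 for leukocyte, −0.010 for endothelial and 0.035 for glandular epithelium markers. The brightest were COL1A1 (6.15 in untreated, 6.16 in YM155 arrays) and THY1, CORO1A and LAPTM5, EGFL7 (6.32 and 6.03) and CLDN5, and GATA4 and APOA1. The ACTB 3' to 5' signal ratio, which RNA integrity and labelling can both move, was 6.61 and 4.54 in untreated replicates 1 and 2, and 4.28 and 7.74 in YM155 replicates 1 and 2. For the dap spike-in control, which is not RNA of the cells, the ratio was 11.9, 11.7, 10.1 and 20.3 on the same arrays.

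**Figure D2:**
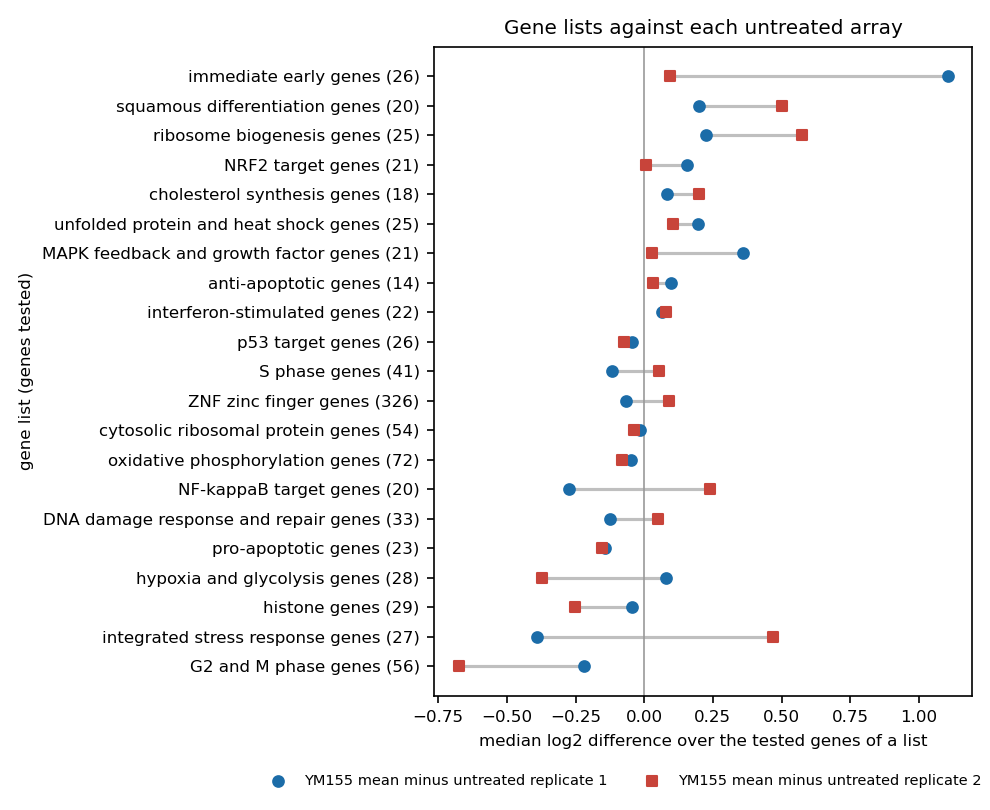
Median log2 difference over the tested genes of each of the 21 lists (horizontal axis), as the mean of the 2 YM155 arrays minus untreated replicate 1 (circles) or untreated replicate 2 (squares); the number of genes tested stands beside each list. The G2 and M phase list lies below 0 against both arrays (−0.22 and −0.68), whereas the integrated stress response list lies on either side (−0.39 and 0.47).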

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

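Array weights and the ACTB ratio as a covariate were chosen after the data were seen, the other alternatives before. The counts of 0 genes higher and 0 lower by limma (1785 at an unadjusted p under 0.05) were 0 under each alternative but 1, with between 445 and 4430 genes at an unadjusted p under 0.05. The exception left out untreated replicate 1: over the arrays left out, the counts ran from 0 to 604 higher, 0 to 521 lower, 0 to 294 at least 2-fold higher and 0 to 295 at least 2-fold lower. Of the 3 ways to split the 4 arrays in pairs, 1 (the real one) gave as many genes at an unadjusted p under 0.05, 1785, against 173 in the higher of the others; 3 splits are too few for a share under 0.05. Array weights were 0.505 for untreated and 1.98 for YM155 arrays. With 2 arrays per group, both arrays of a group must get the same weight. The weights therefore leave each difference unchanged and cannot show which untreated array is off. Same-numbered arrays did not deviate together (correlation across probe sets −0.033). That compares a single difference per group, so it cannot show whether same-numbered arrays shared a culture or day, which the labels do not say. With the replicate block the counts were 0 and 0 (1413 at an unadjusted p under 0.05), and with the ACTB ratio 0 and 0 (1169). BIRC5 was negative under each of its 14 alternatives, from −0.54 to −0.061, and not called in any. With an estimated correlation (adjusted p = 0.706 each) and with fry (adjusted p from 0.278 to 0.54) the list calls ended, at means of −0.46 for G2 and M phase, −0.20 for pro-apoptotic, 0.60 for immediate early, 0.22 for unfolded protein and heat shock, 0.32 for NRF2, 0.38 for ribosome biogenesis and 0.45 for squamous genes. In the other 14 alternatives the calls of the G2 and M phase, ribosome biogenesis and squamous lists held, with means over arrays left out from −0.68 to −0.24, 0.19 to 0.57 and 0.36 to 0.53. The pro-apoptotic call ended with the mean of a gene's probe sets (−0.12), without suffixed probe sets (−0.076), with the stricter filter (−0.20) and with the trend in variance (−0.20, adjusted p = 0.0719). With the replicate block, calls appeared for the cholesterol (0.26, adjusted p = 0.0361) and histone lists (−0.25, adjusted p = 0.0453) and no other list call changed; with array weights, for cholesterol (0.26, adjusted p = 0.04) and histones (−0.25, adjusted p = 0.0402); with the ACTB ratio, for cholesterol (0.28); with the mean of probe sets, for histones (−0.28). The cause was not tested for any of these.

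Over the arrays left out, list means ran from −0.23 to −0.17 (pro-apoptotic), 0.057 to 1.15 (immediate early), 0.15 to 0.30 (unfolded protein and heat shock), 0.25 to 0.39 (NRF2), −0.69 to 0.13 (integrated stress response), −0.59 to 0.15 (hypoxia and glycolysis), −0.41 to −0.090 (histone), 0.18 to 0.34 (cholesterol), −0.051 to 0.43 (MAP kinase), −0.26 to 0.097 (NF-kappaB), −0.18 to 0.0095 (DNA damage), −0.068 to 0.080 (S phase), −0.022 to 0.057 (p53), −0.094 to 0.092 (zinc finger) and −0.027 to 0.00053 (ribosomal protein). The hypoxia list was called lower without untreated replicate 1 (adjusted p = 5.94e-05) and higher without untreated replicate 2 (adjusted p = 0.0447). Calls also appeared without untreated replicate 2 for the integrated stress response (lower, adjusted p = 1.70e-06), MAP kinase (higher, adjusted p = 0.00228) and cholesterol lists (higher, adjusted p = 0.00705), without YM155 replicate 2 for cholesterol (higher, adjusted p = 0.00562), and without untreated replicate 1 for histones (lower, adjusted p = 0.00184). Zinc finger genes turned positive without the filter (0.011), with the stricter filter (0.0024), with quantile normalization (0.031) and with centring (0.0076), p53 targets negative with the stricter filter (−0.012), and NF-kappaB targets positive without suffixed probe sets (0.053). Single genes turned with other probe sets: DBP (0.022), IDI1 (−0.10) and XRCC4 (0.059) without suffixed ones, and ZNF451 with the mean (−0.049). Over the arrays left out, the sign turned for CCN2 (−0.021 to 3.42), ANKRD37 (−2.43 to 0.66), BNIP3 (−2.02 to 0.090), LSS (−0.10 to 1.13), RPL39L (−0.32 to 0.89), EGFR (−0.14 to 0.56), ILF2 (−0.37 to 0.15), LAPTM5 (−0.14 to 0.36), NONO (−0.22 to 0.18), AIFM1 (−0.27 to 0.0053), GATA4 (−0.084 to 0.28), CLDN5 (−0.055 to 0.12), COL1A1 (−0.069 to 0.095), THY1 (−0.14 to 0.0094) and APOA1 (−0.059 to 0.025). Leaving out 1 array leaves a lone array that is assumed to vary like the other group, and a fit of 3 arrays.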

Other observations

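The splicing factor groups, metallothioneins, antisense transcripts and single genes below were chosen after their values were seen, from 15 groups looked at by symbol. All tests here were set after the results were seen, except that on gene length. Of the SR splicing factors, which promote exon recognition, the 9 SRSF genes tested and TRA2A and TRA2B had positive differences (median 0.51 log2), with the YM155 arrays above the untreated ones for 7 and overlapping for SRSF4, SRSF5, SRSF10 and SRSF11. None passed: the values ran from 0.016 for SRSF10 (limma adjusted p = 0.992) upward, with SRSF6 at 1.48 ± 0.15 (SE; limma adjusted p = 0.163), SRSF7 at 1.13 ± 0.26 and SRSF3 at 0.59 ± 0.12. Of the 43 probe sets of these 11 genes, 37 were positive. DDX5, a helicase that also acts in splicing, was positive in its bright probe set too (1.32), which is annotated with several genes. That probe set read 11.19 and 10.02 log2 in untreated replicates 1 and 2 and 11.85 and 12.00 in the YM155 arrays. The size of its difference thus depended on the untreated array. Metallothionein genes, which encode metal-binding proteins, were positive in 7 of 7 (median 0.40), with MT1F at 0.68 ± 0.25 and MT1G at 0.57 ± 0.25, beside the zinc exporter gene SLC30A1. MT2A, at 13.86 log2 in YM155 replicate 2, was near the top of the signal range, where differences can be understated. Against untreated replicate 2 alone the metallothionein median was 0.18, and untreated replicate 2 was 0.51 above replicate 1. Genes of antisense and divergent transcripts had a median of −0.040 over 450 genes, which was −0.11 against untreated replicate 1 and −0.0079 against untreated replicate 2.

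The untreated arrays differed from each other widely. Untreated replicate 2 stood above replicate 1 for HSPA6, a strictly inducible heat shock gene, by 4.86 log2, CCN2 by 3.45, the hypoxia-inducible genes NDRG1 (3.41), HILPDA (3.09) and ANKRD37 (3.09), and the immediate early genes FOS (3.05) and EGR1 (2.87). It stood lower for SLC1A4 (−2.67), CUTALP (−2.63) and NCOA5 (−2.45). HSPA6 was at 3.85 in untreated replicate 1, 8.71 in replicate 2 and 3.87 in the YM155 mean.

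The first pattern followed up was that the 2 untreated arrays were at least 2-fold apart at 1690 probe sets. The YM155 arrays had the larger gap in the ACTB ratio and only 56 such probe sets, so a 3' bias of that kind parted few probe sets. That gap was shared by spike-in controls, whose signal does not come from the cells. The phe control's ratio was 0.967 in YM155 replicate 1 and 3.71 in replicate 2. The gap therefore does not test RNA degradation, which stays open. Untreated replicate 1 was nearer to YM155 replicate 1 (739) than to untreated replicate 2, but not as near as the YM155 arrays to each other. The spread between the YM155 arrays may be technical, so this does not settle whether labels were exchanged between the groups. A YM155 sample from another culture under an untreated label stays possible, and a sample from outside these groups was not tested. A candidate explanation is a different state of the cultures, such as density, medium or handling: the integrated stress response list, fixed beforehand, differed by −0.99 in median (below each of 10000 matched random lists) and the hypoxia list by 0.42. A culture state and an array batch would both part these 2 arrays, the labels name neither (the codes B1 and B2 in the YM155 titles are unexplained), and which untreated array is the better reference stays open.

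The second was the positive differences of SR splicing factor genes. Their medians against untreated replicates 1 and 2 were 0.51 and 0.59, which decides nothing on its own, because the group was picked for its values on these arrays. The YM155 arrays had the largest gap in the ACTB ratio and differed by 0.071 in median, which argues against a 3' bias of that kind as the whole cause. Because spike-in controls shared that gap, it does not test RNA degradation. Whether the positive differences go beyond genes of like signal is not settled by matched lists, because the group was picked for its values. A hypothesis that stays open is that SR transcripts may be part of the response of KYSE410 cells to YM155, which needs other cultures, because culture differences between the groups were not tested.

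The third was a prediction written before the data were examined, that a block of transcript elongation would lower long genes most. Over 10 equal groups of the 14023 genes with a RefSeq span (GRCh38.p14), the median of the group of longest genes was 0.033 above that of the shortest (95% bootstrap interval over genes 0.011 to 0.057), against a predicted gap of −0.1 or below. Against untreated replicate 1 the gap was −0.027 and against untreated replicate 2 it was 0.082, both outside that interval, which leaves out the spread between arrays. The data thus gave no sign of a loss of long transcripts of that size at 6 h, and smaller effects stay open.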
